A study of Caenorhabditis elegans with 8 samples.

How the data were processed

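Ribosome-protected fragments were measured in 8 libraries of C. elegans N2 worms, 4 of young adults and 4 of L4 worms. Per the labels, the worms hatched from an egg preparation and were grown on NGM plates with NA22 bacteria. The values are RPKM as deposited: the authors divided reads per CDS by the feature length and the reads of the library. How reads that map to several places were counted, and which features the lengths cover, is not given in the sources used here. The submitters' notes name bcl2fastq 1.8.4, Bowtie2 2.2.4 and STAR 2.4 without the role of each.

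Whole read numbers, feature lengths and library totals were recovered from the steps between RPKM values with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. All 19649 CDS with a value came out whole within a tolerance of 0.0001, and 856 of the 20505 CDS were at 0 in every library. Between 99.6% and 99.9% of each library's total reads lay in the table. Of the recovered lengths, 25.0% were multiples of 3, so they are called feature lengths. Sequence names were matched to locus tags for gene symbols, and 20051 matched while 454 did not. No genome sequence was used, so the identity of near-identical copies (vit-3 and vit-4, actins, major sperm proteins, nspc genes and histones) could not be checked, and their single values are uncertain.

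Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an abundance trend) on log2(RPKM + 1), two-sided, at a Benjamini-Hochberg threshold of 0.05. CDS needed an RPKM of at least 1 in at least 2 libraries of the comparison. Isolation and library preparation were fitted together on the 4 young-adult libraries, which leaves 1 residual degree of freedom per CDS. The young-adult libraries carry the same specimen number, so their spread is technical. Stage was fitted on all 8 libraries, 4 against 4, with every library kept as labelled. The crossed contrast of the young-adult libraries, the residual of their fit, gave a scale of the noise together with any interaction of isolation with preparation.

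For each contrast the named CDS were the 10 with the largest rise and the 10 with the largest fall among those called, with a mean RPKM of at least 10 in the higher group and the same sign in both matched pairs, or for stage no overlap between the groups. Up to 4 members of each list with the highest mean RPKM could also be named. Other CDS named in the report were chosen after their values were seen where it says so. The library 8 examples vit-6, sqt-1 and fat-7, and the genes given with list counts outside the 4 most occupied members, were chosen after their values were seen.

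The 24 gene lists, the fits, the filters, the rule for named CDS and most of the alternatives listed last were set before the data were examined. Lists covered cytosolic and mitochondrial ribosomal proteins, elongation and initiation factors, aminoacyl-tRNA synthetases, proteins encoded by the mitochondrial genome, oxidative phosphorylation, cuticle collagens, molting and apical matrix, vitellogenins, oocyte and eggshell, germ line, major sperm proteins, sperm, muscle, intestine, nervous system, histones, chaperones, proteasome, ER translocation, glycolysis and TCA cycle, actin and tubulin, and heterochronic regulators. They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. The estimated version draws on the residual degrees of freedom, only 1 for isolation and library preparation. It could hardly call any list there, so a list lost in those contrasts says little about robustness. Lists with fewer than 5 tested members were not tested.

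The labels do not tie a table column to a gel window, so the planned comparisons of each window with 28 to 30 nt, and the naming rule for them, were not run. The 6 pairs of L4 libraries were described instead, with gene lists set against 10000 random lists matched on RPKM.

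On simulated data with 200 changed CDS, the isolation fit recovered 81.0% of changes of 0.5 and 99.0% of changes of 1 on the log2 scale. Of its calls, 11.3% were false, above the nominal 5%, with 23 unchanged CDS called among the 9979 tested, changed ones included. The library preparation fit recovered 76.0% and 100% with 5.88% false calls, and the stage fit 94.0% of changes of 1 and 100% of changes of 2 with 3.00% false calls. These rates describe the simulated data only. The stage fit as run called 5264 of 13592 CDS, against 200 changed in the simulation. Its median SE was 0.238, but the SE of vit-5 was 2.00. The simulated stage rates therefore cannot be taken as those of the fit with L4 library 8 in.

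Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at an RPKM of 10, quantile normalization, median centring, no abundance trend, other model terms, fits on more libraries, leaving out each library, and an estimated correlation. Voom on the recovered reads, fits with all libraries but L4 library 8, list results without it and list counts with median centring were added after the data were seen. Figures were drawn with matplotlib 3.10.9.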

Results

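Ribosome-protected fragments, the pieces of mRNA that a translating ribosome shields from nuclease, were sequenced from whole worms of the C. elegans wild-type strain N2. The table held a ribosome occupancy in RPKM (reads scaled by the length of the feature and by the reads of the library) for 20505 coding sequences (CDS) in 8 libraries. Of these, 4 libraries came from young adults and crossed 2 ways of isolating monosomes, a sucrose gradient or a gel filtration column, with 2 library preparations, the submitters' own protocol (called in-house here) or a commercial ribosome profiling kit. The other 4 came from the fourth larval stage (L4) and differed in the gel window from which fragments were excised: 25 to 30, 28 to 30, 28 to 35 or 26 to 34 nt. Each combination had 1 library. The L4 columns are numbered 5 to 8, and no label ties a number to a window, so these libraries are named by number. The reads recovered from the RPKM steps came to 32494131 for the in-house gradient library, 25502243 for in-house column, 38132794 for kit gradient and 18018744 for kit column. L4 libraries 5 to 8 held 26078844, 21814060, 4999364 and 3684924 reads. RPKM values do not separate mRNA abundance from translation, because no matched mRNA library was used here.

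Monosome isolation was compared within young adults, which asks whether the simpler column gives the same occupancies as the gradient. Cytosolic ribosomal protein CDS gave lower values on the column: 68 of 77 fell, none rose, and the median log2 difference (column minus gradient) was -0.33. Among the most occupied, rps-29 went from 8395 ± 3624 RPKM on the gradient to 6112 ± 2744 on the column (SD, n = 2 libraries each; log2 difference -0.46, SE 0.03), and rps-23 from 6102 ± 1151 to 4763 ± 833 (-0.36, SE 0.03). Cuticle collagens, which build the worm's exoskeleton, moved the other way: 52 of 98 rose, 2 fell, and the median was +0.32. The collagen col-119 rose from 3778 to 5597 RPKM (+0.56, SE 0.04) and col-140 from 5024 ± 124 to 6523 ± 269 (+0.38, SE 0.03). The set test called both lists with a preset correlation and neither with an estimated one (adjusted p = 0.525). With 1 residual degree of freedom the estimated version could hardly call any list. The SD of each pair of libraries includes the difference between the preparations, which the SE does not.

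Single CDS rose by more than these lists. The ribosome biogenesis gene utp-20 rose from 7.61 to 20.4 RPKM (log2 difference +1.31, SE 0.07), the giant muscle kinase unc-22 from 8.76 to 20.1 (+1.11, SE 0.06), the chitin synthase chs-1 from 25.5 to 54.6 (+1.07, SE 0.05) and stt-3, a subunit of the oligosaccharyltransferase of the endoplasmic reticulum (ER), whose gradient libraries averaged 81.9 RPKM (+1.02, SE 0.04). The C-type lectin gene clec-223 (+1.05), ubr-4 (from 7.06 to 15.3 RPKM), T20D3.11 (+1.00) and the ABC transporter mrp-7 (+0.94) also about doubled. The remaining members of the top 10 were F43E2.6, which rose from 0.409 to 13.7 RPKM (+3.22), and msp-10, at 3.86 RPKM on the gradient, which rose 2.83-fold. The 10 CDS that fell most were mostly known by a sequence name alone. Y46G5A.39 had the largest fall (-3.95, SE 0.87), and it rested on 158 RPKM in the in-house gradient library against 4.96 in the kit gradient library. The next were fipr-5 (-1.09), W07A12.8 (-0.82), F19F10.3 (-0.76), Y48G1C.13 (-0.73), W02A2.9 (-0.68), F53F4.16 (-0.68), C43E11.12 (-0.67), F07C3.9 (-0.64) and Y56A3A.28 (-0.63). The call of Y46G5A.39 was lost with a pseudocount of 5. With no abundance trend it was lost too, as were those of W07A12.8, Y48G1C.13, F07C3.9 and Y56A3A.28. All 20 had the same sign with both library preparations, as the rule for naming them required.

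Several other lists also had lower values on the column. Major sperm proteins, the abundant motility proteins of nematode sperm, fell for 21 of 25 members and rose for 1, with a median of -0.40 and msp-64 at 197 RPKM on the gradient and 146 on the column. Histones fell for 26 of 40 with no rise (median -0.28, or -0.16 with a trend on feature length removed; his-72 from 351 to 265 RPKM). Of 71 mitochondrial ribosomal proteins 37 fell and 6 rose (median -0.18; mrpl-12 at -0.34). Of 40 nuclear-encoded subunits of oxidative phosphorylation 20 fell and 5 rose (median -0.13; cox-6B at -0.46, cox-7C at -0.40). Muscle genes went both ways, with 20 of 34 falling and 9 rising: the troponin C gene pat-10 fell by 0.39 and the tropomyosin gene lev-11 by 0.24, while unc-22 and, chosen after their values were seen, the giant protein genes unc-89 (+0.56) and ttn-1 (+0.45) rose. ER translocation and signal recognition genes were also mixed, 10 of 21 higher and 4 lower (4 and 4 with median centring), with sec-61.A at +0.55 and the small subunit sec-61.G at -0.35.

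Aminoacyl-tRNA synthetases rose for 10 of 20 members with no fall (median +0.12, or +0.02 with the length trend removed). Actins and tubulins rose for 6 of 17 with no fall (median +0.16, or +0.09 with it removed; act-4 at +0.17, tba-2 at +0.15). Intestinal genes rose for 14 of 44 with 4 falls (8 and 5 with median centring; median +0.08; asp-1 at +0.20, asp-3 at +0.38). Glycolysis and TCA cycle genes rose for 16 of 40 and fell for 4 (12 and 8 with median centring), although the most occupied ones, mdh-2 (-0.36) and enol-1 (-0.23), fell. Sperm and spermatogenesis genes fell for 12 of 33 and rose for 1. Lists that the set test did not call were initiation factors (9 higher, 8 lower of 35), elongation factors (1 and 3 of 8), molting and apical matrix genes (2 and 0 of 17), vitellogenins (1 and 0 of 6), oocyte and eggshell genes (8 and 16 of 35), germ line genes (7 and 5 of 32), nervous system genes (4 and 6 of 40), chaperones (9 and 13 of 32), proteasome subunits (2 and 8 of 31), heterochronic regulators (0 and 2 of 13) and the ER translocation genes given above (adjusted p = 0.0974). With median centring 6 synthetases and 3 actins and tubulins rose with no fall, and the balance turned for initiation factors (7 higher, 9 lower), vitellogenins (0 and 1) and germ line genes (5 and 6).

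In all, limma called 4511 of 11569 CDS at an adjusted p under 0.05, 2292 higher on the column and 2219 lower, but of these 9 rose and 8 fell by more than 2-fold. The SD of the isolation difference across CDS was 0.28 on the log2 scale, against 0.12 for the crossed contrast of the same 4 libraries. The crossed contrast holds neither main effect, but it holds any interaction of isolation with preparation along with the noise. Centring each library on its median changed the split to 1701 higher and 2703 lower. The set test with a preset correlation called the ribosomal proteins (adjusted p = 2.13e-24), cuticle collagens (3.65e-10), histones (2.58e-08), major sperm proteins (4.16e-08), mitochondrial ribosomal proteins (6.86e-06), oxidative phosphorylation subunits (0.000653), synthetases (0.00473), actins and tubulins (0.00542), muscle genes (0.0148), intestinal genes (0.0461), sperm genes (0.0483) and glycolysis and TCA cycle genes (0.0483). None held with an estimated correlation, where the lowest adjusted p = 0.525. That version had 1 residual degree of freedom and could hardly call any list, so it cannot decide. Histones were lost although their estimated correlation, -0.0026, was lower than the preset 0.01. The list calls therefore rest on the preset correlation alone. Adjusted over the list alone, 70 ribosomal proteins, 26 histones and 21 major sperm proteins fell, 41 mitochondrial ribosomal proteins fell and 8 rose, and 56 collagens rose and 2 fell. The counts higher and lower over the list alone were 5 and 20 for oxidative phosphorylation, 11 and 0 for synthetases, 5 and 0 for actins and tubulins, 10 and 21 for muscle, 14 and 4 for intestine, 1 and 12 for sperm, and 16 and 5 for glycolysis and the TCA cycle. All 4 libraries carry the same specimen number, so these p-values measure technical spread only. No CDS passed when the isolation term was fitted on all 8 libraries, whose wider spread includes the L4 libraries (0 adjusted, 232 at an unadjusted p under 0.05 in limma).

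**Figure D1:**
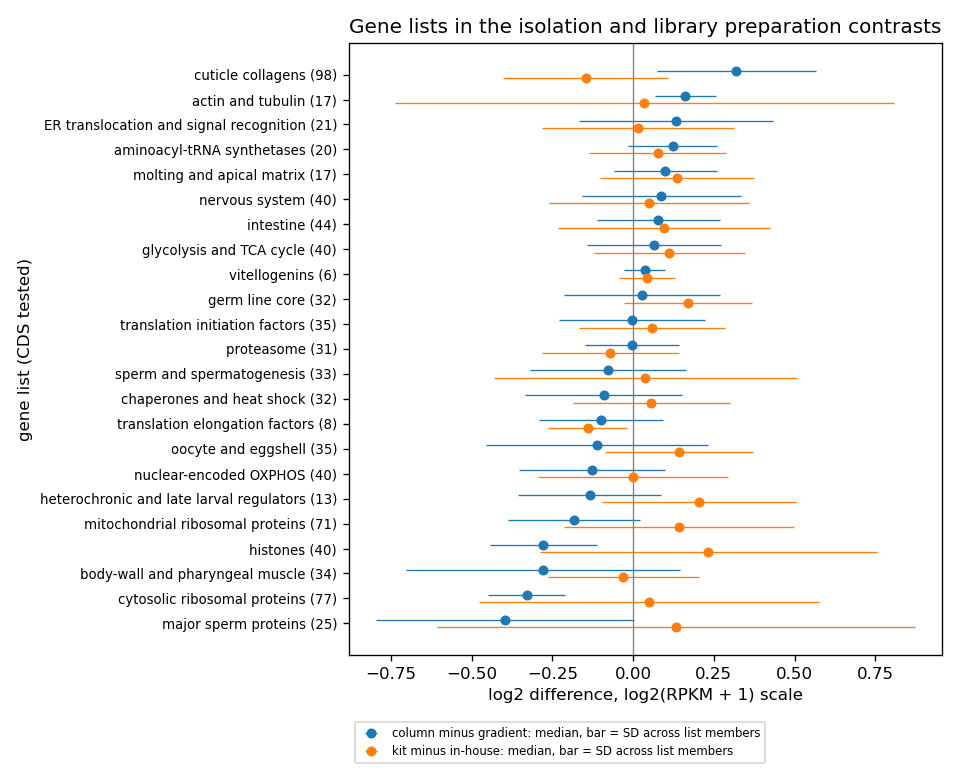
Median log2 difference, on the log2(RPKM + 1) scale, of 23 gene lists for column minus gradient (blue) and kit minus in-house (orange) in the 4 young-adult libraries, with bars for the SD across list members and the number of CDS tested in parentheses. Cuticle collagens had a median of +0.32 for isolation and -0.15 for library preparation, while cytosolic ribosomal proteins had -0.33 and +0.05 (-0.07 with median centring), with a wider SD of 0.53 for library preparation.

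Library preparation was compared in the same 4 libraries, to ask whether the kit and the in-house protocol give the same occupancies. The largest rise in the kit was that of the actin gene act-1, from 17.5 and 21.6 RPKM in the 2 in-house libraries to 148 and 188 RPKM in the 2 kit libraries (log2 difference +3.04, SE 0.05, limma adjusted p = 7.04e-05). The ribosomal protein gene rpl-37.2 rose from 22.1 to 132 RPKM (+2.54), the glutaredoxin gene glrx-5 from 23.2 to 98.9 (+2.05), the antimicrobial-peptide-like gene nlp-33 from 63.5 to 217 (+1.76) and T27E9.2 from 360.5 to 1039 (+1.52). The others among the 10 largest rises were ZK1248.20 (+2.29), K08D8.11 (+1.71), the major sperm protein gene msp-81 (+1.68), F18E3.12 (+1.63) and C15C8.7 (+1.52). The 10 largest falls included CDS of a nematode-specific peptide family, nspc-2 from 30.2 to 4.48 RPKM (-2.49), nspc-7 from 109 to 27.6 (-1.95), and the sperm-specific family gene ssp-11 from 15.5 to 4.24 (-1.66). F13E9.16 (-1.60), cylc-1 (-1.51), sup-35 (-1.28), C33G8.2 (-1.24), the neuropeptide gene flp-10 (-1.13) and fipr-5 (-1.12) fell too, and drd-10 fell from 366 to 164 RPKM (-1.15). Several of these belong to families of near-identical copies (actins, major sperm proteins, nspc genes), for which reads may have been split between members, so their single values are uncertain.

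Highly occupied CDS of the same function often moved apart. Of 77 cytosolic ribosomal proteins 31 rose and 27 fell (35 and 27 when adjusted over the list alone; 23 and 33 with median centring), with rps-29 at -0.93 and rpl-18 at -0.82 while rpl-37.1, chosen after its value was seen, stood at +1.15; the SD across the list was 0.53. Of 25 major sperm proteins 11 rose and 8 fell (9 and 12 with median centring). More histones rose than fell, 20 and 8 of 40 (16 and 12), and so did mitochondrial ribosomal proteins, 35 and 13 of 71 (21 and 19). Among oxidative phosphorylation subunits 15 rose and 11 fell of 40 (8 and 15 with median centring), with cox-7C falling from 1491 ± 340 to 684 ± 111 RPKM (-1.11). Intestinal genes rose for 15 and fell for 9 of 44 (10 and 14 with median centring), with spp-5 at +0.68 and the cathepsin genes asp-1 at -0.48 and asp-3 at -0.53. Of 98 cuticle collagens 26 fell in the kit, 5 rose and 67 did not pass, the same numbers when adjusted over the list alone, with a median of -0.15 and col-20 at -0.44 (41 fell and 3 rose with median centring). The set test called this list with a preset correlation and not with an estimated one (adjusted p = 0.950), which had 1 residual degree of freedom. Elongation factors fell for 5 of 8 with no rise (8 and 0 with median centring; eef-1A.1 at -0.34, from 14318 to 11305 RPKM), and proteasome subunits for 10 of 31 with 4 rises (18 and 2 with median centring; pas-3 at -0.60). Relative to the median of all CDS, which lay 0.10 higher in the kit, the medians of these 3 lists were -0.25, -0.24 and -0.17. The other lists, none called by the set test, had these counts higher and lower in the kit: initiation factors 12 and 4, synthetases 8 and 2, molting and apical matrix genes 4 and 1, vitellogenins 2 and 0, oocyte and eggshell genes 16 and 4, germ line genes 15 and 1, and sperm genes 3 and 10. Muscle genes had 10 and 6, nervous system genes 8 and 4, chaperones 12 and 8, ER translocation genes 6 and 9, glycolysis and TCA cycle genes 17 and 7, actins and tubulins 5 and 5, and heterochronic regulators 4 and 0. With median centring the balance turned or went for most of these: initiation factors had 8 and 7, synthetases 5 and 7, molting genes 0 and 1, vitellogenins 0 and 3, oocyte genes 9 and 7, muscle genes 5 and 13, nervous system genes 6 and 9, chaperones 7 and 13, and glycolysis and TCA cycle genes 11 and 14. Germ line genes had 7 and 3, sperm genes 2 and 11, ER translocation genes 2 and 9, actins and tubulins 4 and 6, and heterochronic regulators 2 and 1.

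For library preparation limma called 4152 of 11569 CDS, 2992 higher in the kit and 1160 lower; 99 of them rose and 19 fell by more than 2-fold. The share of calls that were higher in the kit, 72.1%, depended on the scaling: it was 48.9% with quantile normalization and 45.3% with median centring. The SD of the difference across CDS was 0.31. The set test with a preset correlation called cuticle collagens (adjusted p = 4.56e-09), elongation factors (0.000265) and proteasome subunits (0.00745). Each was lost with an estimated correlation (set test, adjusted p = 0.950), but with 1 residual degree of freedom that version could hardly call any list. Fitted on all 8 libraries, limma called 0 CDS for library preparation, with 384 at an unadjusted p under 0.05.

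The L4 libraries were made to compare gel windows. Libraries 5 and 6 were close to each other over 12856 CDS (Pearson r = 0.996 across CDS, which are not independent replicates; SD of the log2 difference 0.20), and library 7 stood a little further off (SD 0.45 from library 5 and 0.46 from library 6). Library 8 differed from the other 3 by an SD of 1.42 to 1.47, with 32.5% to 34.6% of CDS apart by more than 2-fold. Between libraries 5 and 6, whose list differences were small, cuticle collagens had a median of +0.13 in library 5 relative to library 6, at percentile 100 of 10000 random lists matched on RPKM. Library 7 had lower values than library 6 for major sperm proteins, by a median of 0.32 (percentile 99.7), and than library 5 for histones, by 0.29 (percentile 99.9). The other pairs were less extreme: 0.22 for major sperm proteins against library 5 (percentile 96.4) and 0.17 for histones against library 6 (percentile 92.5). Cuticle collagens had a median of -0.095 in library 6 relative to library 7 (percentile 0.01), and +0.05 in library 5 relative to library 7 (percentile 25.0). Single CDS with large differences among libraries 5 to 7, chosen after their values were seen, included mrpl-41, which stood at 195 RPKM in library 5, 193 in library 6 and 775 in library 7, tin-9.1 at 161 in library 5 and 686 in library 7, and rpl-37.2 at 84.8, 217 and 29.6 RPKM in libraries 5, 6 and 7. Each window had 1 library, so none of these differences has a replicate check.

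The library labelled L4 with number 8 carried a young-adult profile. Its Pearson r with the 4 young-adult libraries was 0.963 to 0.975 over 13592 CDS, against 0.774 to 0.785 with L4 libraries 5 to 7. The yolk protein gene vit-6 stood at 8032 RPKM in library 8, at 7424 ± 238 in the young adults (SD, n = 4 libraries) and at 23.2 ± 1.91 in libraries 5 to 7 (SD, n = 3). The cuticle collagen sqt-1 stood at 5.14 RPKM in library 8, at 1.26 ± 0.0824 in young adults and at 2475 ± 81.5 in libraries 5 to 7. The fatty acid desaturase gene fat-7 did not follow: it was at 10.1 RPKM in library 8, 193 ± 51.0 in young adults and 0.934 ± 0.317 in libraries 5 to 7.

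**Figure D2:**
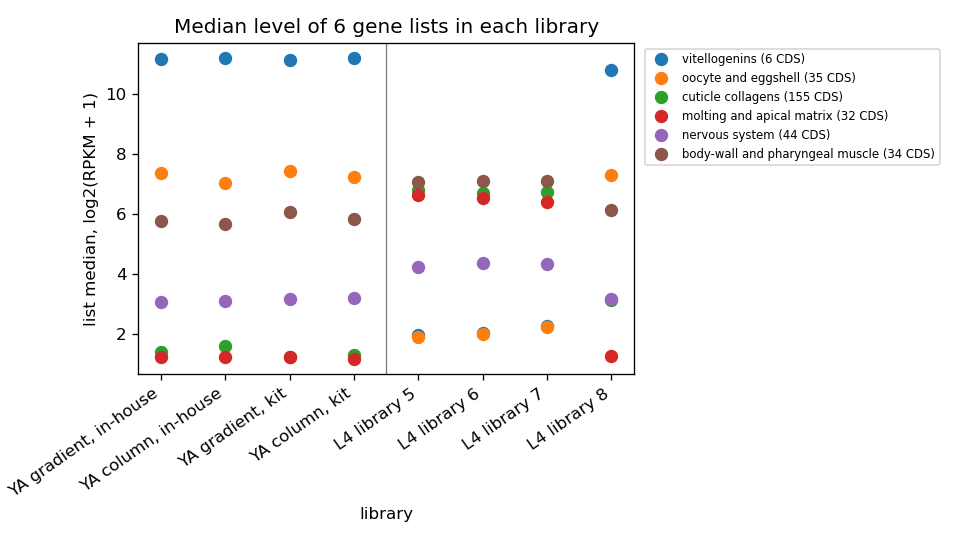
Median log2(RPKM + 1) of 6 gene lists (colours, with the number of CDS) in each of the 8 libraries, young adults left of the line and libraries labelled L4 right of it. The vitellogenin median was 10.8 in L4 library 8 and 1.97 to 2.27 in L4 libraries 5 to 7, and the molting and apical matrix median was 1.27 against 6.41 to 6.65.

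Young adults were compared with L4 across the series. Stage, experiment, worm collection and parts of the protocol change together here and cannot be told apart. All 4 young-adult and all 4 L4 libraries entered, with library 8 as labelled. In the stage fits, SEs and p-values measure the spread between the libraries of 1 stage, not between worm cultures. With library 8 in, that spread includes the gap between library 8 and L4 libraries 5 to 7, so it is not one between protocols alone. For vit-5 the SD of the L4 libraries was 712 RPKM with library 8 and 0.337 without it. All 6 vitellogenins were higher in young adults, with a median log2 difference of +6.48, led among named genes by vit-5 (+7.54, SE 2.00). Oocyte and eggshell genes rose for 33 of 35 (median +3.44), among them puf-5 (+6.08), the chitin-binding eggshell genes cpg-2 (+5.79) and cbd-1 (+5.68), and the yolk receptor gene rme-2 (+5.75). The uterine gene ule-3 (+6.03), fat-7 (+5.99) and the vitellogenins vit-3 (+6.71), vit-4 (+6.57) and vit-1 (+6.36) completed the 10 largest rises under the naming rule. That rule takes only CDS whose young-adult and L4 values do not overlap. Among the called CDS that it left out were cpg-1 (+6.83), vit-2 (+6.39) and vit-6 (+6.17). The set test called both lists, and neither with an estimated correlation (adjusted p = 0.516 with library 8 in). By the same rule the 10 largest falls were all cuticle collagens. They were sqt-1 (-7.94), dpy-4 (-7.87), dpy-5 (-7.83), col-138 (-7.76), dpy-13 (-7.71), col-38 (-7.68), sqt-2 (-7.63), col-71 (-7.62), col-48 (-7.60) and col-73 (-7.59). The copies vit-3 and vit-4 are near-identical, so reads may be shared between them.

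Leaving out library 8, one of the alternatives set before the data were examined, gave larger differences with smaller errors. Those errors measure the spread between protocols, and again not that between worm cultures. The list medians and counts without library 8 were added after its profile was seen. Over 4 young-adult and 3 L4 libraries, sqt-1 fell by 10.10 on the log2 scale (SE 0.11), and bli-2 (-9.74), dpy-4 (-9.72) and lon-3 (-9.33) fell as well. The yolk gene vit-5 rose to 1915 ± 52.4 RPKM (+9.91, SE 0.14), the eggshell gene cpg-1 from 1.60 to 1370 RPKM (+9.03), ule-5 to +9.02, C10G8.4 to +9.02 and stha-3 to +8.98. The vitellogenins vit-3 (+8.66), vit-4 (+8.57) and vit-2 (+8.54), ZK813.1 (+8.56) and the collagen col-143 (+8.52) followed, and the other named falls were sqt-2 (-9.70), dpy-13 (-9.62), dpy-5 (-9.60), col-138 (-9.53), col-38 (-9.42) and col-71 (-9.40). On this scale, log2(RPKM + 1), a fold change is understated where the lower level is near or under 1 RPKM.

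Cuticle collagens split: without library 8, 124 of 155 fell and 26 rose, and with it 121 fell and 23 rose. The collagens most occupied in young adults rose without library 8, col-140 from 93.6 ± 10.5 to 5774 ± 882 RPKM (+5.92), col-119 from 27.6 ± 3.96 to 4687 ± 1197 (+7.33), col-20 (+5.00) and col-181 (+4.37). Of 32 molting and apical matrix genes 29 fell and 1 rose without library 8 (28 and 0 with it): the lipocalin gene lpr-3 fell from 836 ± 191 to 1.33 ± 0.215 RPKM (-8.47), noah-1 from 642 to 5.98 (-6.51) and noah-2 from 552 to 5.05 (-6.50), whereas grd-3 rose (+1.94) and did not pass with library 8 (+1.34, adjusted p = 0.0695). Heterochronic regulators fell for 11 of 16 and rose for 4 without library 8 (6 and 1 with it). With median centring 7 fell and 4 rose without library 8, and 4 fell and 3 rose with it. Without library 8 the molting-cycle gene lin-42 fell from 70.4 ± 4.94 to 1.18 ± 0.293 RPKM (-5.04), and lin-41, also expressed in oocytes, rose from 3.55 to 79.4 (+4.14).

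The median CDS was 0.34 lower in young adults without library 8 and 0.26 lower with it, and the following medians are given relative to that shift. Without library 8, oocyte and eggshell genes rose for 34 of 35 (relative median +4.96). Proteasome subunits rose for 24 of 31 with no fall (+0.89), synthetases for 14 of 20 with no fall (+0.89; kars-1 from 173 to 395 RPKM) and cytosolic ribosomal proteins for 53 of 77 with 3 falls (+1.02). Germ line genes rose for 16 of 33 and fell for 6 (+0.66), with the Argonaute gene csr-1 rising from 66.6 to 217 RPKM. Muscle genes fell for 31 of 34 (-0.68; pat-10 from 5163 ± 1167 to 1671 ± 282 RPKM) and nervous system genes for 40 of 44 (-0.67; flp-9 from 86.4 to 13.6 RPKM). Fewer members passed with library 8 in: 10 germ line genes rose and 3 fell, and the counts were 13 proteasome subunits, 26 ribosomal proteins, 8 synthetases, 22 muscle genes and 27 nervous system genes. With median centring and library 8 in, 23 proteasome subunits, 39 ribosomal proteins, 16 synthetases and 18 germ line genes rose, and 13 muscle genes and 15 nervous system genes fell. With median centring and without library 8, 28 proteasome subunits, 18 synthetases, 67 ribosomal proteins and 25 germ line genes rose, and 24 muscle genes and 33 nervous system genes fell. Sperm and spermatogenesis genes fell for 25 of 39 and rose for 2 without library 8 (15 and 8 with median centring; ssp-16, at 201 RPKM in L4, fell by 2.21 on the log2 scale). Chaperones rose for 14 and fell for 16 of 35 (16 and 13 with median centring; the ER chaperones pdi-2 at -2.78 and crt-1 at -1.82). Intestinal genes rose for 9 and fell for 21 of 44 (16 and 10 with median centring). Oxidative phosphorylation subunits fell for 29 of 40 and mitochondrial ribosomal proteins for 44 of 71 as deposited, but their medians lay only 0.33 and 0.19 below the shift, and with median centring 14 and 15 fell. With library 8 in, the counts higher and lower, with those after median centring in parentheses, were 1 and 12 (5 and 5) for sperm genes and 4 and 10 (6 and 7) for intestinal genes. They were 9 and 14 (13 and 10) for chaperones, 2 and 20 (4 and 3) for oxidative phosphorylation subunits and 0 and 14 (9 and 1) for mitochondrial ribosomal proteins. Without library 8 the set test called none of the sperm (adjusted p = 0.104), chaperone (0.697), intestinal (0.697), oxidative phosphorylation (0.0718), mitochondrial ribosomal protein (0.121) and heterochronic lists (0.324). Nor did it call the remaining lists, which had these counts higher and lower: histones 11 and 18 (18 and 13 with median centring), glycolysis and TCA cycle genes 7 and 15 (13 and 4), ER translocation genes 1 and 7 (7 and 5), major sperm proteins 4 and 4 (13 and 1), initiation factors 8 and 6 (22 and 3), elongation factors 4 and 2 (6 and 2), and actins and tubulins 4 and 11 (8 and 11). With library 8 in, these were histones 0 and 11 (7 and 7), glycolysis and TCA cycle genes 6 and 7 (11 and 1), ER translocation genes 0 and 2 (5 and 1), major sperm proteins 3 and 1 (10 and 1), initiation factors 6 and 3 (16 and 1), elongation factors 2 and 2 (5 and 1), and actins and tubulins 2 and 8 (7 and 3). With library 8 in, the set test did call major sperm proteins (adjusted p = 0.000951), initiation factors (0.0119) and oxidative phosphorylation subunits (0.00506) with a preset correlation. Each was lost with an estimated one (adjusted p = 0.586, 0.516 and 0.586). The 12 CDS of the mitochondrial genome reached at most 5.45 RPKM in any library. Only 8 of them could be named and entered the list, and the 2 of these that passed the filter were not called.

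Across all 8 libraries limma called 5264 of 13592 CDS, 1507 higher in young adults and 3757 lower; with median centring the split was 2955 higher and 2148 lower. Without library 8 it called 9352 of 13494, 3059 higher and 6293 lower, or 4937 and 4171 with median centring. Adjusted over the list alone, 34 oocyte genes rose with library 8 in and 34 without it, and 122 and 124 collagens fell. With library 8 in, the set test called 13 lists with a preset correlation and none with an estimated one (lowest adjusted p = 0.516). Without it, molting genes (adjusted p = 0.0148 with an estimated correlation), vitellogenins (0.0254), oocyte genes (0.0120), nervous system genes (0.0254) and proteasome subunits (0.0302) held. The calls of muscle genes (adjusted p = 0.0637), synthetases (0.135), ribosomal proteins (0.291), collagens (0.314) and germ line genes (0.314) were lost. Leaving out any single library other than 8 left 381 to 1892 CDS, and keeping only the 2 in-house young-adult libraries left 5 in limma (3808 at an unadjusted p under 0.05), so the counts with library 8 in are not stable.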

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

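The tests of the gel window, of young-adult material, of secreted and membrane families and of near-identical copies were chosen after the result was seen. Of 54 measures, list medians and library statistics over the 4 libraries of a stage, 7 had 1 library far from the other 3. Chance gives about 1 in 20 for a single measure, but these share libraries and are not independent. In each of the 7 the library was L4 library 8. Its median log2(RPKM + 1) was 3.16 for cuticle collagens (6.71 to 6.81 in L4 libraries 5 to 7), 1.27 for molting and apical matrix genes (6.41 to 6.65), 10.8 for vitellogenins (1.97 to 2.27) and 7.30 for oocyte and eggshell genes (1.92 to 2.26). It was 2.29 for sperm genes (3.93 to 4.16), 6.13 for muscle genes (7.09 to 7.12) and 3.17 for nervous system genes (4.23 to 4.37).

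Low read depth was excluded as the cause, since fewer reads add noise and can hardly raise a Pearson r across CDS with the young-adult mean. That r was 0.974 for library 8 and 0.766 for L4 libraries 5 and 6. Thinned to the reads of library 8, libraries 5 and 6 reached at most 0.764, an outcome nearly fixed in advance. The gel window as labelled was excluded too. Each window holds 28 to 30 nt, so libraries of the same worms would share those fragments, but the vitellogenins allow at most 0.280% of their fragments in library 8 to be in common with libraries 5 to 7. The molting list allows at most 11.3% of its fragments in libraries 5 to 7 to be in common with library 8. Young-adult material may be the source, through a wrong label or worms past L4, since the oocyte list went 93.8% of the way from libraries 5 to 7 to the young adults (quartiles 82.3 and 108). Which of these 2 applies was not tested.

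Isolation differences rose with feature length (Spearman rho 0.371 across CDS, 0.334 in the in-house pair and 0.359 in the kit pair), so length was tested as a cause of the list differences. With a smooth length trend removed, the pooled median of 142 ribosomal protein, histone and major sperm protein CDS went from -0.33 to -0.22 (SD 0.21), and that of the collagens stayed at 0.32, so length is excluded as the whole cause of either. Histones alone went from -0.28 to -0.16. Some other called lists also shrank: synthetases went from 0.12 to 0.02, glycolysis and TCA cycle genes from 0.06 to 0.01, and actins and tubulins from 0.16 to 0.09. Intestinal genes went from 0.08 to 0.05, and sperm and spermatogenesis genes from -0.08 to -0.05. Oxidative phosphorylation subunits went from -0.13 to -0.09 and mitochondrial ribosomal proteins from -0.18 to -0.13. For those lists length stays open as a part or the whole of the difference. Muscle genes changed less, from -0.28 to -0.25. Some secreted and membrane families may be favoured on the column. The 191 CDS of 10 other such families had a median of 0.22, at percentile 100 of matched random lists. Of them 72 were called higher and 3 lower. They include clec-223 and mrp-7 of the top 10 rises, which had been seen before the families were chosen. Not every secreted group shared the rise. With the length trend removed the median was -0.15 for vitellogenins and -0.004 for molting and apical matrix genes. No biological explanation was tested, since the libraries share a specimen.

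Kit differences of short and multi-copy CDS may come from few fragment positions in a short CDS. From an RPKM of 10 the SD of the difference in the shortest of 4 length classes was 2.38 times that in the longest. However, the crossed contrast had a ratio of 1.86 as well. Reads shared between near-identical copies may add to the kit differences: the SD over major sperm proteins, 0.74, lay at percentile 100 of matched random lists. That test is not specific, because cytosolic ribosomal proteins lay at percentile 98.9 and histones at 83.3. Of the actins act-1 rose by 3.04, act-2 by 0.14, act-3 by 0.77 and act-4 by 0.28, and their sum by 0.32, so no copy fell in the kit. No biological explanation was tested.

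Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many CDS as the real one, the real one itself. It had 5264 CDS against at most 2 in any other. This cannot exclude chance for the stage count, because the 8 libraries are not interchangeable. The young-adult libraries share a specimen and the L4 libraries come from another experiment. Chance variation between worm samples was not measured and cannot be excluded. Stage, experiment, worm collection and parts of the protocol remain confounded.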

How the results depend on the processing

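Voom and the fits without L4 library 8, apart from the planned leave-one-out count, were chosen after seeing the data. No called list median changed sign under any alternative run. Sign changes of named CDS that the main fit did not call were not counted. Among named CDS that it called, 3 values reversed. With quantile normalization they were isolation gene eef-1B.1 (0.0283) and isolation gene hsp-1 (0.0969), and with median centring library gene vit-2 (-0.00490). The cause was not tested.

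For isolation, 0 CDS were called by limma with all 8 libraries in the fit (232 at an unadjusted p under 0.05), 0 with no term for the other factor (1651), 0 with all libraries but L4 library 8 (2104), and 0 to 0 in leave-one-out fits on all libraries (10 to 15); voom called 5431. For library preparation these were 0 (384), 6 (1846), 4 (2009) and 0 to 0 (46 to 54), 2626 with no abundance trend, and 5398 with voom. By construction, fits on more libraries or without the other term take in more spread. For the counts with no abundance trend and with voom, the cause was not tested. In leave-one-out fits a lone library of a combination is assumed to vary like the others.

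For stage, 3308 CDS were called with an RPKM of at least 10, where fewer were tested, 609 with isolation and library terms, and 5 with in-house young adults only. Leave-one-out gave 381 (without L4 library 5) to 9352 (without L4 library 8), with 449 without L4 library 6, 482 without column kit, 628 without column in-house, 1049 without gradient kit, 1485 without L4 library 7 and 1892 without gradient in-house.

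Gene lists called fell to 0 with an estimated correlation in the isolation, library preparation and stage contrasts. For isolation and library preparation this was nearly fixed in advance by the 1 residual degree of freedom. Without L4 library 8, stage had 10 with the preset correlation and 5 with the estimated one. The SD across CDS of the isolation, library preparation and crossed contrasts was 0.344, 0.381 and 0.167 with a pseudocount of 0.1 and 0.212, 0.233 and 0.0732 with 5; the crossed SD was 0.0737 with an RPKM of at least 10. The lowest and highest SD between L4 libraries were 0.269 and 1.91 with a pseudocount of 0.1, 0.138 and 1.096 with 5, 0.175 and 1.57 with an RPKM of at least 10, and 0.213 and 1.41 with quantile normalization. Depth limits L4 libraries 7 and 8 most, with 4999364 and 3684924 reads.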

Other observations

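The comparisons here were chosen after the values were seen. L4 library 8 was not identical to the young adults. CDS over 2-fold above all 4 young-adult libraries were counted only from 10 RPKM in library 8. These were 28 of 155 cuticle collagens, each among the 124 that fell, 0 of 32 molting and apical matrix genes, and 135 of 13592 CDS. Another 46 lay over 2-fold below, counted only where every young-adult library had at least 10 RPKM. Lower CDS such as sqt-1 (5.14 RPKM in library 8) were left out. The molting list had a median log2(RPKM + 1) of 1.27 in library 8, so many members lay under this floor and its 0 says little. The collagen col-39 stood at 63.2 RPKM in library 8, 17.1 in young adults and 728 in L4 libraries 5 to 7, and col-77 at 48.3, 7.51 and 3118. The metallothionein gene mtl-1 stood at 78.4 RPKM in library 8, 7.07 in young adults and 7.30 in L4 libraries 5 to 7, and the heat shock gene hsp-16.2 at 11.6, 0.431 and 62.2.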
